A study of Homo sapiens with 47 samples.

How the data were processed

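MicroRNAs (miRNAs) were measured in primary human trophoblasts, the epithelial cells of the placenta, on 47 one-colour Agilent arrays, with RNA extracted by a miRNeasy kit and labelled with the Agilent kit per the labels. The cells came from 4 placentas, here called replicates 1, 2, 4 and 5. They were kept in standard culture (20% oxygen) or moved to hypoxia at time 0, which the series design places 4 h after plating. The labels conflict on the hypoxic level: the series design gives 0% oxygen and the treatment protocol 1%, so the condition is called hypoxic without a percentage. There were 3 replicates per condition at 6 h and 4 at each other time, and 2 further arrays of replicate 1 at 8% oxygen. The labels mark 3 arrays of replicate 1 as repeats, without saying whether the culture or the RNA was repeated; a repeat was averaged with the first array of its group, which left 44 samples.

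Per the file headers, the scanner files hold linear spot intensity, read by Agilent Feature Extraction 10.7.3.1, with background and spatial trend subtracted and no normalization between arrays. These files also hold flags of 0 or 1 for detection, signal well above background, saturation and deviant spots, per the file headers. The deposited value table holds a log2 value per miRNA and array for 939 miRNAs. The submitters' processing notes name RMA without stating which of its steps were run. Against the log2 mean spot signal of the same array, its values had a slope of 1.03 to 1.36 and a correlation across miRNAs of 0.97 to 0.988. Both kinds of file were used.

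The arrays carried 2689 probes for 851 human and 88 viral miRNAs. For each array, the background-subtracted intensity was averaged over the spots of a probe, leaving out spots that the scanner software marked as deviant, and then over the probes of a miRNA. Each array was scaled to its 75th percentile over the 161 human miRNAs detected on every array. Values under a floor, the 5th percentile of the scaled signals of detected miRNAs (-7.61 on the log2 scale), were set to it. The values were then taken as log2. A level of 0 on this scale is the array's 75th percentile. The 350 human miRNAs detected on at least 4 arrays were tested. miRNA names are those of the deposited files, with the prefix for human left out; 12 names differed between the annotation versions in the files.

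The number of arrays limits the precision. The 75th percentile of the signal ranged from 200.1 to 1356 per array (median 866.6), and 206 to 336 human miRNAs were detected per array (median 276). On each array 0 spots were saturated, and 44 to 102 of the tested miRNAs lay at the floor on an array (median 72). A miRNA was called well above background where the scanner software marked the majority of the spots of any of its probes so. Where a miRNA was so on no array of a group, a bound was computed. For it, that group was raised to the lowest signal of any miRNA well above background on the same array. The words "at least" mark this bound. The other group kept its values, those at the floor included, and sampling error was left out. Where arrays of that other group were not well above background either, the bound is not a strict minimum. For list medians with dim members at their bound, a bound under 1-fold, or a miRNA well above background in neither group, counted as 0.

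Comparisons used limma 3.58.1 in R 4.3.3, with the package data.table (1.17.8), and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. For the mean over times, the hypoxic minus standard difference was averaged over the times of each replicate and the 4 values were tested against 0. For each time, for the F tests and for standard culture, 1 fit held the groups from 0 h to 72 h with the replicate as a block. The block is in the main design because the series design states that plates of a preparation were divided between the conditions, and replicate numbers stand for placentas. Paired samples also deviated together: the correlation of deviations from the group means was 0.38 to 0.85 between conditions of the same replicate and at most 0.4 between different replicates.

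Lists of miRNAs, fixed by name, were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry; adjusted values are over the lists of a comparison. The lists were C19MC, C14MC, the miR-371 to miR-373 cluster, miR-17-92 and paralogs, and the miR-200, let-7, miR-29 and miR-34 families. Further lists held miRNAs reported to respond to hypoxia in cancer cell lines and miRNAs reported in hypoxic trophoblasts. Others held markers of erythroid, leukocyte, endothelial, stromal, and muscle, neural and liver cells. Names were matched without their arm, star and locus marks. Passenger strands, named with a star, were therefore members too, though the lists do not name them. In a supplied gene table of assembly GRCh38.p14, the 45 tested C19MC miRNAs and the 5 of the miR-371 to miR-373 cluster were all on chromosome 19 and the 8 of C14MC on chromosome 14. The single 8% arrays were not tested; list medians were set against 10000 random lists matched on mean expression.

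The text names miR-210 in each comparison. For the mean over times and for 72 h against 0 h it names the 10 largest rises and 10 largest falls among those past the threshold and changed the same way in every replicate. It further names the 3 largest changes per time, the 3 smallest p-values per F test, and up to 4 members per list, besides list members past the threshold, which were chosen after their values were seen. The design, the lists, this rule and most of the other settings tried were fixed before the data were examined. These settings were no replicate block, the slide as a block, normexp background (offset 50), 3 other scalings, RMA, and the deposited values. They were further the scanner software's summary per miRNA, 2 other filters, a lower floor, no repeat arrays, only the 2 groups compared, 1 fit for the mean over times, and each replicate left out. For the mean over times, the settings without the replicate block and with the slide as a block also used 1 fit of all samples. Such a fit counts the times of a replicate as separate samples. Settings chosen after seeing the data left out arrays of low signal, an array with a strong spatial trend, or miRNAs with no spread. Another setting so chosen replaced bright local backgrounds.

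The fits were tested on simulated data with 60 changed miRNAs among 350. For the mean over times, 93.3% of log2 changes of 0.5 were recovered, and 5 unchanged miRNAs were called in that run. The simulated change was the same at each time and in each replicate, so this share is a best case. At single times 36.7% (6 h) to 56.7% (48 h) were recovered, against 76.7% (6 h) to 93.3% (24 h) of log2 changes of 1. For 72 h against 0 h the shares were 43.3% and 76.7%. In 20 simulations with no change, 0 to 2 gave any call. The simulated noise was independent between miRNAs and samples and had no floor, so the rate of false calls on the real arrays may differ. The viral miRNAs were left out of the comparisons.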

Results

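The series profiled miRNAs, short RNAs that repress target messenger RNAs, in primary trophoblasts of 4 placentas. Cells were sampled in standard culture at 0, 6, 12, 24, 48 and 72 h and in hypoxic culture from 6 h on. Of 851 human miRNAs on the arrays, 206 to 336 were detected per array. Values below are log2 changes with their SE from limma unless stated, with n = 4 replicates except at 6 h, where n = 3.

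The first comparison asked which miRNAs changed in hypoxia, averaged over 6 h to 72 h. miR-210, the miRNA best known as a target of hypoxia-inducible factor, rose 3.45-fold (95% confidence interval 3.03 to 3.93, adjusted p = 0.00453), and its log2 difference lay between 1.63 and 1.99 in the 4 replicates. It was well above background on 19 of 21 hypoxic but 3 of 19 standard arrays. The next largest rises were those of both arms of the miR-193b hairpin, miR-193b* at 0.73 ± 0.066 (adjusted p = 0.0142) and miR-193b at 0.57 ± 0.098 (adjusted p = 0.0347). miR-30c (0.42), miR-32 (0.40), miR-148a (0.32), miR-20b (0.305), miR-20a (0.30), miR-483-3p (0.27) and miR-17 (0.25) rose by less, with adjusted p from 0.0175 to 0.0444. miR-584 fell most, by 1.05 ± 0.14 (adjusted p = 0.0222).

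miR-371-3p changed by -0.94 ± 0.058, miR-373 by -0.92 ± 0.077 and miR-372 by -0.85 ± 0.057, each with adjusted p = 0.0142 and lower in 4 of 4 replicates. These 3 belong to a cluster expressed in pluripotent cells and placenta. miR-29b-1*, the passenger strand of a miR-29 hairpin, changed by -0.89 ± 0.065 (adjusted p = 0.0142). miR-516a-3p (-0.64) and miR-520c-3p (-0.57), both of the placental cluster C19MC, and miR-150* (-0.61), miR-503 (-0.61) and miR-140-5p (-0.57) also fell, with adjusted p from 0.0142 to 0.0334. Of these, miR-503 lay at the floor in both conditions at 6, 12 and 24 h. It was well above background on 1 of 21 hypoxic and 6 of 19 standard arrays. In all, 61 of 350 tested miRNAs passed the threshold, 24 higher and 37 lower, and all 61 moved the same way in every replicate. The direction of the bulk depended on the scaling. Scaled to the 75th percentile over all human miRNAs, 47 were higher and 15 lower, and with the percentile outside C19MC 68 and 28. Quantile normalization gave 32 and 27, RMA 57 and 43, and the values deposited by the authors 56 and 37. With the slide as a block beside the replicate block, 110 miRNAs passed. That setting tested the mean in 1 fit of all samples, a change of test that raised the count by itself, as given below.

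On each of 6 slides hypoxic and standard first arrays of the same replicate and time lay together, 16 pairs in all. The mean difference ranged over slides, which also differ in their times, from 0.99 to 3.79 for miR-210, -2.25 to -0.41 for miR-584 and -1.54 to -0.29 for miR-371-3p. In the 2 scan sessions, the first of which holds only replicate 1, these were 1.69 and 1.71, -0.87 and -0.94, and -0.60 and -0.98. RMA gave smaller changes, among them 1.10 for miR-210, -0.54 for miR-584 and -0.52 for miR-371-3p. Without replicate 2 limma called 0 miRNAs (83 at an unadjusted p under 0.05), with miR-210 at 1.78 (adjusted p = 0.0889). With normexp background correction it called 0 (31 unadjusted), and 51 once bright local backgrounds were replaced. Scaling ended the call of miR-503 (adjusted p = 0.0758 with the percentile over all human miRNAs, 0.086 with quantile normalization) and of miR-17 (0.0574 with quantile normalization).

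Among the fixed lists, the miR-371 to miR-373 cluster fell as a group under hypoxia. Of its 5 tested members 3 fell and 0 rose (4 and 0 adjusted over the list alone). Its median was -0.85 (camera adjusted p = 0.00562, adjusted p = 0.504 with an estimated correlation, fry adjusted p = 0.0137), and -1.29 to -0.28 over slides. miR-371-3p, miR-372 and miR-373 lay at the floor on all 5 arrays of a second set (the 3 repeat and both 8% arrays of replicate 1) and on 0 of its 11 first arrays. Without the repeats they changed by -0.89, -0.76 and -0.84, each with adjusted p = 0.0104. Of the miR-17-92 clusters and their paralogs, which promote proliferation, 5 of 16 members rose and 0 fell (7 and 0 adjusted over the list alone): miR-17, miR-20a, miR-20b, miR-92a (0.12) and miR-93 (0.17). Their median was 0.10 (camera adjusted p = 0.00179, adjusted p = 0.504 with an estimated correlation, fry adjusted p = 0.0144), and -0.07 to 0.64 over slides. Scaled to the 75th percentile over all human miRNAs it was 0.253. Normexp background correction ended both list calls, with a median of -0.30 (adjusted p = 0.0909) for the miR-371 to miR-373 cluster and a reversed one of -0.114 (adjusted p = 0.129) for miR-17-92.

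C19MC, a primate-specific cluster expressed mainly in placenta, moved both ways. Of its 45 tested members 4 rose and 5 fell (the same numbers adjusted over the list alone). The risers were miR-516b (0.10), miR-518a-5p (0.20), miR-518c* (0.15) and miR-520d-3p (0.18), and the largest falls after miR-516a-3p and miR-520c-3p were miR-520f (-0.53) and miR-526b* (-0.50). The median was 0.07, the mean 0.0065, and 36 members lay above 0. Camera placed the list upward (adjusted p = 0.00179, adjusted p = 0.504 with an estimated correlation), and fry gave adjusted p = 0.173. That call ended without the replicate block (adjusted p = 0.0939), with the slide as a block (0.0518), in 1 fit of all samples (0.0798) and with miRNAs detected on every array (0.0589). Over slides the median was -0.00803 to 0.488, and with the percentile over all human miRNAs it was 0.215.

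In the miR-29 family, which represses genes of the extracellular matrix, 3 of 6 members fell and 0 rose (3 and 0 adjusted over the list alone). These were miR-29b-1*, miR-29a (-0.49) and miR-29b (-0.43), while miR-29c was at -0.07 (adjusted p = 0.275). Its median of -0.25 did not set it apart from other miRNAs (camera adjusted p = 0.058, adjusted p = 0.504 with an estimated correlation), but did in 10 of 22 other settings, among them the fit without the replicate block (adjusted p = 0.0244). Over the 22 the median was -0.434 to -0.0694. Fry gave adjusted p = 0.0137, and over slides the median was -0.44 to 0.08. Of 8 tested C14MC members, from an imprinted cluster on chromosome 14, 0 passed (0 adjusted over the list alone). All 8 values were negative, with a median of -0.20 (-0.114 with dim members at their bound, camera adjusted p = 0.182, fry adjusted p = 0.0137). In the miR-200 family of epithelial cells 0 of 3 passed and 1 rose adjusted over the list alone (median 0.15, camera adjusted p = 0.182). In the let-7 family 0 of 7 passed (0 adjusted over the list alone, median 0.04, camera adjusted p = 0.342). In the miR-34 family, which responds to DNA damage, 0 of 4 passed (0 adjusted over the list alone, median 0.20, camera adjusted p = 0.182).

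Of 15 tested members of the list of miRNAs reported to rise in hypoxic cancer cell lines, only miR-210 rose in the mean over times. In the same list miR-23a (-0.27), miR-23a* (-0.45), miR-24 (-0.30) and miR-27a (-0.40) fell (1 rose and 5 fell adjusted over the list alone). The passenger strand miR-23a* is a member only through the name of miR-23a. The median was 0.07 (camera adjusted p = 0.375), and fry's test for changes in either direction gave adjusted p = 3.7e-04. With the 75th percentile outside C19MC each of the 4 falling miRNAs lost its limma call (adjusted p from 0.0519 to 0.0605). Another list, of miRNAs reported in hypoxic trophoblasts, had 15 tested members, passenger strands included. Some perhaps come from related cultures, so it is not independent evidence. Of these miR-205 (0.23), miR-210, miR-335 (0.17), its passenger strand miR-335* (0.23) and miR-93 rose. In the same list miR-27a and miR-424 (-0.56) fell (6 rose and 5 fell adjusted over the list alone). The median was 0.06 (camera adjusted p = 0.182, fry adjusted p = 0.0137). Lists of other cell types did not stand apart by camera. Of 4 erythroid markers 0 passed (0 adjusted over the list alone, median -0.07, camera adjusted p = 0.375). Among 4 members of the leukocyte list miR-150* fell (1 rose and 2 fell adjusted over the list alone, median -0.06, camera adjusted p = 0.581). It is the passenger strand of the listed marker miR-150, which was not among the tested miRNAs. Among 4 stromal markers miR-125b changed by -0.15 (1 fell adjusted over the list alone, median -0.12, camera adjusted p = 0.22). Of 4 markers of muscle, nerve and liver, a background list, miR-122 fell (at least 1.04-fold, 1 fell adjusted over the list alone, median -0.25, camera adjusted p = 0.182). As miR-122 was well above background on 0 of 21 hypoxic and 1 of 19 standard arrays, its bound is not a strict minimum. With dim members at their bound, the medians of the erythroid, leukocyte and background lists were 0, 0.00105 and -0.171. Fry gave adjusted p from 0.017 to 0.0443 for the 4 lists of cell markers. Over the other settings the medians of the let-7, cancer-line, leukocyte and stromal lists took both signs. The endothelial markers had 0 tested members.

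The second question was when the changes appeared. miR-210 changed by 0.32 ± 0.22 at 6 h (adjusted p = 1), 0.84 ± 0.19 at 12 h (adjusted p = 0.0239), and 1.60 ± 0.19 at 24 h (adjusted p = 5.3e-07). It reached 2.76 ± 0.19 at 48 h (adjusted p = 4.2e-12) and 3.07 ± 0.19 at 72 h (adjusted p = 2.5e-13). In the main processing the rise was at least 2.9-fold at 24 h, 6.41-fold at 48 h and 5.84-fold at 72 h. Over 21 other settings, its log2 value was 0.216 to 1.77 at 24 h, 0.201 to 2.92 at 48 h and 0.609 to 3.59 at 72 h. It passed in 20 of the 21 at each of these times. Normexp background correction as planned, not among the 21, reversed it at 48 h, as given below. miR-29b-1* was lowest at 24 h (-1.61 ± 0.18, adjusted p = 2.2e-07), after -0.905 ± 0.18 at 12 h (adjusted p = 0.0111). At 12 h miR-193b* also rose (0.635 ± 0.15, adjusted p = 0.0239), and these 2 and miR-210 were the 3 miRNAs past the threshold. The 12 h calls were fragile: of 21 other settings miR-210 passed in 11, miR-29b-1* in 10 and miR-193b* in 9, and all 3 calls ended without the replicate block and without any 1 of the 4 replicates. miR-372 fell by 1.04 ± 0.16 at 24 h (adjusted p = 3.8e-05). At 48 h miR-584 changed by -1.95 ± 0.21 (at least 3.79-fold, adjusted p = 5.8e-08) and miR-503 by -1.59 ± 0.21 (adjusted p = 6.4e-07, well above background on 1 of 4 hypoxic arrays). At 72 h miR-584 changed by -2.20 ± 0.21 (at least 3.07-fold, adjusted p = 2.7e-09) and miR-371-3p by -1.86 ± 0.17 (adjusted p = 1.7e-09). The rise of miR-20a was seen late, at 0.58 ± 0.12 at 48 h (adjusted p = 5.1e-04) and 0.76 ± 0.12 at 72 h (adjusted p = 1.5e-05).

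**Figure D1:**
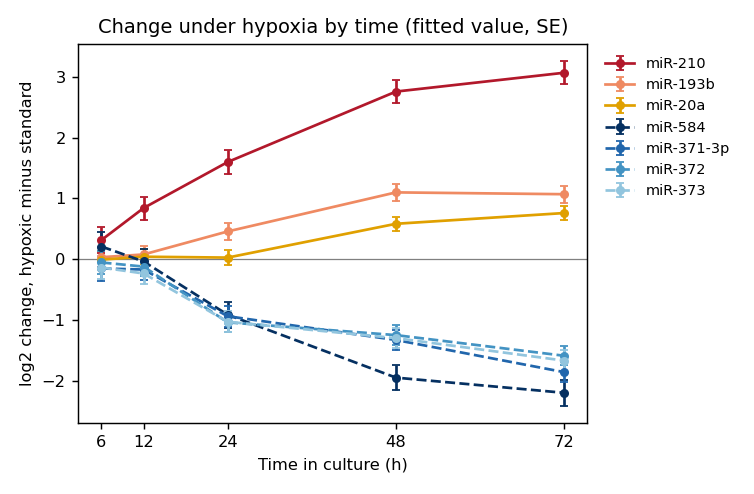
Fitted log2 change (hypoxic minus standard, vertical axis) of 7 miRNAs against time in culture in hours; points are limma estimates and bars their SE (n = 3 replicates at 6 h, otherwise 4). The fitted values reach 3.07 for miR-210 and -2.20 for miR-584 at 72 h, each with 1 of the 2 groups not well above background, and miR-371-3p, miR-372 and miR-373 fall from 24 h on.

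The median of the miR-371 to miR-373 cluster was -0.10, -0.17, -0.94, -1.25 and -1.59 from 6 h to 72 h. At 72 h 5 of 5 members passed the threshold. The median of miR-17-92 and paralogs was 0.24 at 48 h, where 7 of 16 rose, and 0.32 at 72 h, where 10 rose. At 72 h, 12 C19MC members rose and 7 fell, and 4 of 8 C14MC members fell (median -0.60). The miR-29 median was lowest at 24 h (-0.56). Of the 15 members of the list from hypoxic cancer cell lines, 1 rose and 3 fell at 48 h (median 0.059). At 72 h 9 of them rose and 4 fell (median 0.40).

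These values moved with the other scalings, RMA and the deposited values. In the miR-371 to miR-373 cluster 3 to 4 of 5 members then passed at 72 h (median -1.56 to -0.967). Of miR-17-92, 4 to 9 rose at 48 h (median 0.25 to 0.411, with 4 at 0.383 for the percentile over all human miRNAs) and 9 to 10 at 72 h (0.314 to 0.753). At 72 h 10 to 28 C19MC members rose and 0 to 7 fell, and 1 to 3 C14MC members fell (median -0.53 to -0.222). The miR-29 median at 24 h was -0.418 to -0.366, again the lowest of the 5 times. From the cancer lines 1 to 5 rose and 0 to 3 fell at 48 h (median 0.117 to 0.168), so the excess of falls there depends on the scaling. At 72 h 7 to 9 rose and 1 to 4 fell (median 0.341 to 0.654).

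Over all tested miRNAs, limma called 0 at 6 h (3 at an unadjusted p under 0.05), 3 at 12 h, 28 at 24 h, 71 at 48 h and 153 at 72 h. Of the 28 at 24 h, 23 passed at 48 h in the same direction, where independent lists would share 3.44. Of the 71 at 48 h, 59 passed at 72 h in the same direction, against 16.3 for independent lists. The F test of the difference between times called 30 miRNAs, led by miR-210 (F = 34, adjusted p = 4.5e-08), miR-584 (F = 24.5, adjusted p = 9.6e-07) and miR-371-3p (F = 17.3, adjusted p = 2.3e-05). The slide as a block gave 0, 3, 26, 51 and 166 calls at the 5 times and 32 in the F test. A fit with no replicate block gave 0 (1 unadjusted), 0 (5 unadjusted), 16, 40 and 78, and 11 in the F test.

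**Figure D2:**
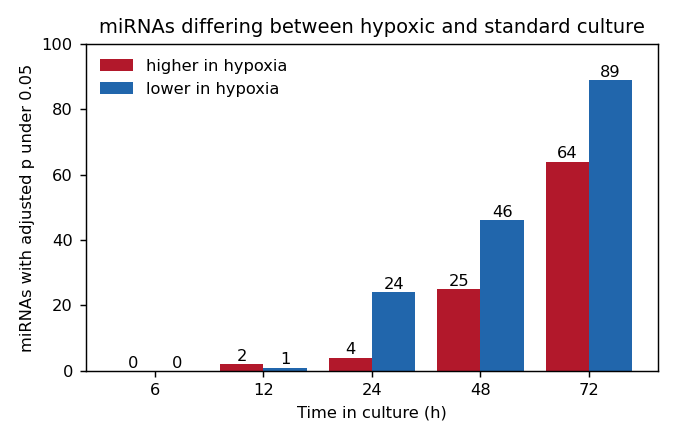
Number of miRNAs with adjusted p under 0.05 (vertical axis, of 350 tested) against time in culture in hours; bars split them into higher and lower in hypoxia. Calls grow from 0 at 6 h to 64 higher and 89 lower at 72 h, a split that turns to 103 higher and 26 lower with the 75th percentile over all human miRNAs.

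Higher and lower calls were 4 and 24 at 24 h, 25 and 46 at 48 h, and 64 and 89 at 72 h. Scaled to the 75th percentile over all human miRNAs they were 2 and 6, 17 and 20, and 103 and 26. The percentile outside C19MC gave 6 and 8 at 24 h and 66 and 31 at 48 h. Quantile normalization gave 30 and 31 at 48 h and 73 and 51 at 72 h, RMA 38 and 30, and 65 and 57. The deposited values gave 36 and 33 at 48 h and 71 and 53 at 72 h. At 12 h, 2 were higher and 1 lower. This became 1 and 0 with the percentile over all human miRNAs or quantile normalization, 2 and 0 with the percentile outside C19MC and 0 and 1 in the deposited values. The median over all tested miRNAs at 72 h was -0.10 in the main scaling and 0.12 with the percentile over all human miRNAs. A small change at 72 h therefore has a direction only relative to the scaling.

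The third comparison followed standard culture itself, in which mononuclear trophoblasts are known to fuse into a syncytium. From 0 h to 72 h, miR-1290 rose 37.4-fold (95% confidence interval 29.8 to 46.9, adjusted p = 4.1e-22). In the same samples miR-1246 rose 20.2-fold (15.9 to 25.7, adjusted p = 2.3e-19) and miR-1268 rose 17.4-fold (11.6 to 26.1, adjusted p = 3.7e-13). Each of these 3 rose in 4 of 4 replicates. miR-1246 and miR-1290 were up by 1.41 and 1.35 on the log2 scale at 6 h, whereas miR-1268 was at 0.82 at 24 h and 2.52 at 48 h. miR-32* (2.69 ± 0.34), miR-371-5p (2.25 ± 0.31), miR-595 (2.23 ± 0.39), miR-373 (2.16 ± 0.17), miR-371-3p (2.04 ± 0.17), miR-22 (1.95 ± 0.13) and miR-140-5p (1.91 ± 0.25) rose too, with adjusted p from 1.6e-13 to 1.7e-05. The rise of miR-32* was at least 4.58-fold, and that of miR-595 ranged from 0.148 to 3.72 on the log2 scale over replicates.

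The largest falls were those of miR-345 (-2.88 ± 0.37), miR-574-3p (-2.81 ± 0.35, at least 4.88-fold), miR-335* (-2.49 ± 0.15, at least 4.17-fold), miR-513a-5p (-2.41 ± 0.36), miR-424* (-2.17 ± 0.23, at least 3.05-fold) and miR-513b (-1.93 ± 0.28). miR-575 (-1.70 ± 0.26), miR-18a (-1.65 ± 0.12, at least 2.14-fold), miR-17 (-1.62 ± 0.11) and miR-1826 (-1.51 ± 0.31) followed, with adjusted p from 1.8e-14 to 1.7e-04 over these 10. At 6 h miR-345 was at -2.08, miR-513a-5p at -2.59, miR-513b at -2.25, miR-1826 at -2.23, miR-424* at -1.96 and miR-575 at -1.85. Much or all of these 6 falls thus lay before 6 h and rests on the 0 h arrays. Whether the 0 h arrays as a set are their source was not tested. The other 4 had changed less by 6 h: miR-574-3p by -0.773, miR-335* by -0.274, miR-18a by 0.0899 and miR-17 by 0.038. miR-210 changed by -1.15 ± 0.19 in standard culture (at least 1.54-fold, adjusted p = 1.2e-05). In all 168 miRNAs passed, 88 higher and 80 lower, of which 113 moved the same way in every replicate. Which direction held the majority depended on the scaling. With the 75th percentile over all human miRNAs 69 were higher and 85 lower, and with that outside C19MC 84 and 80. Quantile normalization gave 74 and 87, RMA 82 and 90, and the deposited values 83 and 90. By the F test 226 changed at some time, led by miR-1290 (F = 266, adjusted p = 6.0e-21), miR-1246 (F = 176, adjusted p = 1.1e-18) and miR-335* (F = 110, adjusted p = 5.4e-16).

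**Figure D3:**
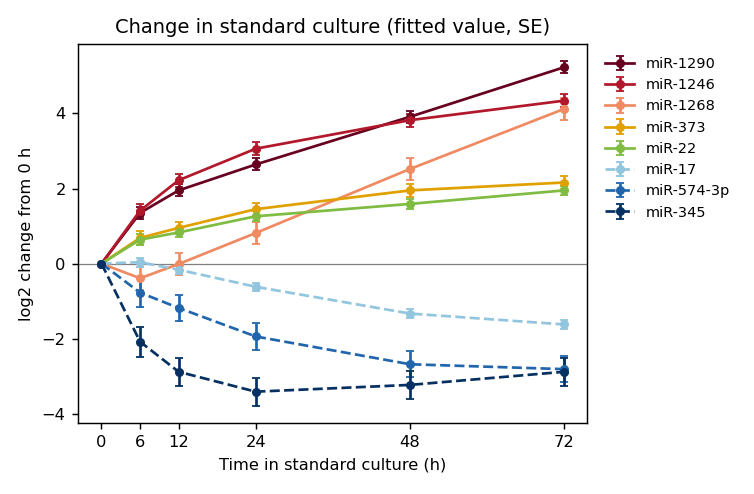
Fitted log2 change from 0 h (vertical axis) of 8 miRNAs in standard culture against time in hours; points are limma estimates and bars their SE (n = 3 replicates at 6 h, otherwise 4). miR-1290, miR-1246 and miR-1268 end between 4.12 and 5.23 at 72 h, while miR-345 is at -2.08 by 6 h.

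The slide as a block gave 131 calls for 72 h against 0 h and 197 for the F test. Only 1 replicate had both times on 1 slide, with a 0 h array from the second set, so no value within slides could be had apart from the set. In a fit of only the 2 groups, 48 miRNAs passed, and miR-595, miR-345, miR-513a-5p, miR-513b, miR-575 and miR-1826 did not, with adjusted p of 0.106, 0.06, 0.0852, 0.0926, 0.0682 and 0.0869. RMA gave smaller falls, among them -1.84 for miR-345, -1.63 for miR-574-3p, -1.37 for miR-335* and -0.82 for miR-18a, and without the 3 arrays of lowest signal miR-513b was at -1.25 and miR-1826 at -0.86.

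In culture the miR-371 to miR-373 cluster rose, opposite to its change in hypoxia. The 72 h standard arrays enter both with opposite sign, which alone favours opposite changes. At 48 h of hypoxia, which shares no array with the change from 0 h to 72 h, the median was -1.25 as given above. All 5 members rose (5 adjusted over the list alone), with a median of 2.04 (camera adjusted p = 8.8e-04, adjusted p = 0.0617 with an estimated correlation, fry adjusted p = 4.7e-14). Without the repeat arrays, at the floor for this cluster, miR-371-3p was at 1.97 and miR-373 at 2.04, both past the threshold. Normexp background correction ended the call of the list (median 0.464, adjusted p = 0.598, and 0.394 once bright local backgrounds were replaced). The miR-17-92 list fell, with 11 of 16 members lower and 1 higher (the same numbers adjusted over the list alone). Its median was -0.63 (camera adjusted p = 2.1e-04, adjusted p = 0.292 with an estimated correlation, fry adjusted p = 3.9e-10). Among its members miR-93 changed by -1.37 ± 0.099 and miR-20b by -1.37 ± 0.11. In the miR-29 family 3 of 6 rose (3 adjusted over the list alone), with miR-29a at 1.33 ± 0.083. The list did not stand apart from other miRNAs (median 0.38, camera adjusted p = 0.247, fry adjusted p = 4.5e-08).

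Of 45 C19MC members, 18 fell and 5 rose (the same numbers adjusted over the list alone). The miRNAs miR-519e* (-1.40), miR-520d-3p (-1.13) and miR-525-3p (-1.12) fell most, and miR-516a-3p rose by 1.38. The median was -0.14 (camera adjusted p = 0.0195, adjusted p = 0.614 with an estimated correlation, fry adjusted p = 2.6e-04). The call ended with the slide as a block (adjusted p = 0.0827) and without replicate 1 (adjusted p = 0.212). C19MC made up 44.6% ± 4.0 (SD, n = 4) of the human miRNA signal at 0 h. At 72 h it made up 32.8% ± 4.8 (SD, n = 4) in standard and 40.5% ± 5.6 (SD, n = 4) in hypoxic culture. In standard culture the share was 49% ± 2.5 (SD, n = 3) at 6 h and 49.9% ± 0.77 (SD, n = 4) at 12 h. It also depends on miRNAs outside the list. In standard culture the level of miR-1246 was 1.06 at 0 h and 5.4 at 72 h, and that of miR-1290 -0.853 and 4.37. A lower share therefore does not by itself show a fall of C19MC. The shares were not tested.

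**Figure D4:**
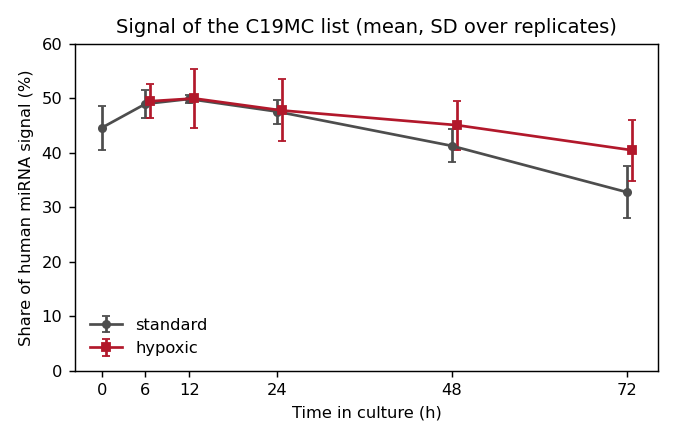
Share of the summed human miRNA signal taken by the C19MC list (percent, vertical axis) against time in culture in hours; points are means over replicates and bars the SD (n = 3 at 6 h, otherwise 4). The share is 44.6% at 0 h, 49.9% in standard culture at 12 h, and 32.8% in standard and 40.5% in hypoxic culture at 72 h. It also depends on the signal of miRNAs outside the list.

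The other lists did not stand apart in culture, with camera adjusted p from 0.163 to 0.939. In C14MC 3 of 8 rose and 2 fell (the same adjusted over the list alone, median 0.27, camera adjusted p = 0.939). The risers miR-127-3p, miR-382 and miR-539 were well above background on 0 of 5 arrays at 0 h and 1 of 4 at 72 h. Their bounds (at least 1.18-, 1.24- and 1.27-fold) are therefore not strict minima. The median reversed with the slide as a block (-0.126) and with miRNAs detected on every array (-0.53), and was 0.974 without replicate 2. The medians of the miR-200, let-7, miR-34, cancer-line, trophoblast, erythroid and leukocyte lists below also took both signs over the other settings. In the miR-200 family 0 of 3 passed (0 adjusted over the list alone, median -0.02). Of 7 let-7 members, let-7e (0.69) rose and let-7d fell (1 and 1 adjusted over the list alone, median -0.01). For let-7d, well above background on 1 of 5 arrays at 0 h and 0 of 4 at 72 h, the fall was at least 1.06-fold. This bound is not a strict minimum either. Of 4 in the miR-34 family, miR-34a (0.555) rose and miR-34b* (-0.435) fell (1 and 1 adjusted over the list alone, median -0.07). In the list from hypoxic cancer lines 5 members rose, among them miR-23a (1.44) and miR-27a (1.17), and 4 fell. The numbers were the same adjusted over the list alone (median -0.10, mean 0.07). In the list from hypoxic trophoblasts 3 members rose, with miR-424 at 1.72, and 5 fell, with miR-205 at -1.39. These numbers too were the same adjusted over the list alone (median -0.05, camera adjusted p = 0.293). Among the cell markers, 0 of 4 erythroid miRNAs passed (0 adjusted over the list alone, median -0.105). Of 4 members of the leukocyte list miR-150*, the passenger strand of the untested marker miR-150, rose by 1.05 (1 adjusted over the list alone, median -0.08, mean 0.15). Of 4 stromal markers miR-125b (0.73) and miR-100 (0.66) rose (2 adjusted over the list alone, median 0.69, camera adjusted p = 0.91). Replicate 2 carried most of this rise: without it miR-125b was at 0.12 (adjusted p = 0.438) and miR-100 at 0.154 (adjusted p = 0.207). Both were past the threshold in only some of the 22 other settings, 16 for miR-125b and 15 for miR-100. The calls of miR-34a (0.223, adjusted p = 0.213) and let-7e (0.388, adjusted p = 0.0658) also ended without replicate 2, and each of these 4 miRNAs rose in 3 of 4 replicates. Leaving out replicate 2 also leaves out the 0 h array of lowest signal (75th percentile 200.1), so it does not tell the placenta from that array. Of the 4 muscle, neural and liver markers, miR-122 (at least 1.3-fold), miR-206 (at least 1.51-fold) and miR-9* (at least 1.65-fold) rose (3 adjusted over the list alone, camera adjusted p = 0.163). Each was well above background on 0 of 5 arrays at 0 h and 1 of 4 at 72 h, so these bounds are not strict minima. The list's fitted median of 1.16 became 0.488 with dim members at their bound.

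A last comparison set 8% oxygen, sampled once at 24 h and once at 72 h from replicate 1, beside the others. With 1 array per group there is no replicate check. The hypoxic repeat arrays were dim, with a 75th percentile of the signal of 475 at 24 h and 286.7 at 72 h. The 8% arrays had 736.5 and 799.8. At 72 h, 101 tested miRNAs lay at the floor on the hypoxic repeat and 88 on the 8% array. Against the hypoxic repeat arrays of the same set and slide, miR-210 was higher in hypoxia by 2.06 at 24 h (at least 4.16-fold) and 3.82 at 72 h (at least 14.2-fold) on the log2 scale. In 8% oxygen it was not well above background at either time (-7.57 at 24 h and the floor, -7.61, at 72 h), so the 72 h difference is set by the floor and the 24 h one rests on a level near it. The bounds hold only for the main processing. With normexp background correction and with RMA the 72 h difference was smaller, as given below. miR-29b-1* was lower in hypoxia than in 8% oxygen, by -2.94 and -1.20. Of the 20 miRNAs named for hypoxia, miR-371-3p, miR-372, miR-373 and miR-503 lay at the floor on both arrays at both times. Of the other 16, 14 at 24 h and 15 at 72 h differed in the hypoxia direction between hypoxia and 8% oxygen. The median difference in that direction was 0.208 and 0.928 for these 16, and 0.13 and 0.86 for all 20. The 20 were chosen partly on these hypoxic arrays, so agreement is favoured. The miR-29 list was the lowest at 24 h (median -0.81, percentile 0.01 among random lists). At 72 h the list from hypoxic cancer lines (median 0.73) and the miR-34 family (median 1.26) lay at percentile 100.

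Compared with standard culture, 13 and 15 of the 20 lay in the hypoxia direction in 8% oxygen at 24 h and 72 h. The median in that direction was 0.05 and 0.32, and for the first hypoxic arrays of that replicate 0.56 and 1.28. miR-29b-1* was instead higher in 8% oxygen than in standard culture, by 1.35 and 0.456, and miR-210, at or near the floor, differed by -0.0619 and 0. The miR-29 list lay above standard culture too (median 0.253 and 0.445, percentiles 97.9 and 99.1 among random lists). The differences between 8% oxygen and standard culture are confounded with the array set. The standard 72 h array of this replicate was also dim, with a 75th percentile of 251. The 8% arrays belong to the second set, on which miR-371-3p, miR-372 and miR-373 lay at the floor on 5 of 5 arrays. In replicate 1, 9 tested miRNAs were lower on each second-set array than on each first-set array, 0 higher. The correlation of the 3 repeat arrays with their first arrays was 0.992 (0 h), 0.993 (hypoxic, 24 h) and 0.986 (hypoxic, 72 h) across miRNAs, which are not independent replicates. The SD of the log2 differences was 0.40, 0.39 and 0.53.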

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

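The test of the 72 h count on the replicates sampled at 6 h was chosen after the result was seen; the other tests in this part were planned before it.

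The number of miRNAs past the threshold grew with time in hypoxia, from 0 at 6 h (3 at an unadjusted p under 0.05, limma) to 153 at 72 h. Differences in array signal as the whole cause are argued against by a fit with the log2 array signal as a covariate, which still called 173 at 72 h and 0 at 6 h. The lower number of replicates at 6 h is argued against as well, since the 3 replicates sampled then gave 122 calls at 72 h. Changes that grow in size were not tested apart from the counts, since all counts come from 1 fit with a common error per miRNA. The SD of the hypoxic minus standard differences over 161 miRNAs detected on every array averaged 0.113 at 6 h and 0.575 at 72 h, and it was 2.98 times as large or more at 72 h in each replicate with both times, which restates the growth and names no source of it. A longer response to hypoxia and a slow decline of the cultures both stay open, untested.

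The hypoxia effect differed between times, by limma's F test of the difference, for 13 of the miRNAs named for the mean over times. The adjusted p was 4.5e-08 for miR-210, 9.6e-07 for miR-584, 2.3e-05 for miR-371-3p and miR-372, 5.4e-05 for miR-373 and miR-503, 1.7e-04 for miR-193b, 0.00256 for miR-17, miR-20a and miR-20b, 0.00535 for miR-32, 0.0126 for miR-140-5p and 0.0266 for miR-29b-1*. For miR-371-3p the fitted change was largest at 72 h, and for miR-29b-1* at 24 h. At 48 h and 72 h miR-210 was well above background on 0 standard and miR-584 on 0 hypoxic arrays, so the order of these times is not shown for them.

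In 10 of 99 groups of values 1 sample lay far from the others, where chance alone gives about 1 in 20. For the mean over times, the log2 difference of 1 replicate was 0.237 for miR-32 (others 0.432 to 0.463), 0.0876 for miR-17 (others 0.295 to 0.324) and -0.562 for miR-584 (others -1.24 to -1.19). The let-7 median of 1 replicate was 0.211 (others 0 to 0.0176). At 48 h, 1 replicate had a miR-210 difference of 2.26, and the others 2.89 to 2.97. From 0 h to 72 h in standard culture, 1 replicate changed by -4.6 for miR-513a-5p (others -1.95 to -1.54) and by -3.77 for miR-513b (others -1.46 to -1.04). The 75th percentile of the signal was 200 on 1 array at 0 h (others 910 to 1200) and 251 on 1 standard array at 72 h (others 852 to 952). In addition, the repeat array of replicate 1 in hypoxia at 72 h had 210 human miRNAs detected (others 261 to 272, with 261 on the first array of that replicate).

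Among the viral miRNA probes, which no comparison used, the scanner software called a median of 9 of 88 miRNAs detected per array (6 to 19), with 5 detected on every array and 54 on none. From 6 h on the mean was 10.9 on 19 standard and 8.95 on 21 hypoxic arrays, a difference that was not tested.

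Other splits of the samples gave fewer calls than the real ones, except at 6 h. For the mean over times 61 miRNAs passed, against 38 in the highest other of 100 regroupings, so that 1 of 100, the real one, gave as many. These regroupings exchanged the conditions at single times of a replicate, though its times are not independent. Such exchanges also partly cancel in the mean of a replicate. Exchanging whole replicates, of which there are 4, gives too few regroupings for a share under 0.05. Of 35 splits per time, 1 gave as many as the real one: 3 against 0 in the highest other at 12 h, 28 against 0 at 24 h, 71 against 12 at 48 h and 153 against 55 at 72 h. These 35 include splits with both samples of a replicate in 1 group, while the real one parts every pair. The 8 that part every pair are too few for a share under 0.05; among them the highest other was 0 at 12 h and 24 h, 2 at 48 h and 43 at 72 h. At 6 h, the 10 splits are too few for a share under 0.05; the real count and the highest other were both 0, so 10 of 10 gave as many. The F test gave 30 calls against 6 over 100 regroupings. For 72 h against 0 h, 168 miRNAs passed, so that 1 of 35 splits gave as many. The highest other gave 154 and is 1 of the 8 that part every pair, again too few for a share under 0.05. Such a split exchanges the times in some replicates and keeps them in the others. The F test of any change in culture gave 226 against 142 over 100 regroupings.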

How the results depend on the processing

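Leaving out arrays of low signal, an array with a strong spatial trend or miRNAs without spread, and replacing bright local backgrounds, were chosen after seeing the data; the other alternatives were planned. From 0 h to 72 h, miR-1290 (4.5 to 5.53), miR-1246, miR-1268, miR-22, miR-371-5p and miR-17 kept their direction and their side of the threshold in all 22 alternatives and in normexp background correction as planned. Apart from the latter, given below, in the mean over times miR-210 (0.242 to 1.9), miR-371-3p, miR-372 and miR-29b-1* kept their direction in all 21 alternatives with a value, and each lost its call in 1, without replicate 2. The miR-17-92 list passed by camera in all 22 of these alternatives in both comparisons, but not with an estimated correlation (adjusted p = 0.504 in hypoxia and 0.292 in culture). Signal over background limits the dim miRNAs: 44 to 102 tested miRNAs lay at the floor per array. Normexp background correction as planned ended the calls of 70 named miRNA results, the most of any setting.

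Without the replicate block the paired counts changed from 3 to 0 at 12 h (5 at an unadjusted p under 0.05, limma), from 28 to 16 at 24 h, from 71 to 40 at 48 h, from 153 to 78 at 72 h, and from 30 to 11 for the difference between times. Of the named miRNA results 11 lost and 4 gained a call without the block. Of the list results 1 lost (C19MC) and 1 gained one (miR-29 family), both in hypoxia. No other call of a named result changed. For the mean over times this setting also used 1 fit of all samples. In 1 fit with the block kept, 1 list result (C19MC) also lost and 1 gained a call. The list changes can therefore not be credited to the block. With the slide as a block, 110 passed in the mean over times in place of 61. That setting also used 1 fit of all samples, which by itself raised the count nearly as far, as given below. The rise can therefore not be credited to the slide.

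Normexp background correction with offset 50 gave 0 calls for the mean over times (31 unadjusted), 0 at 12 h (0 unadjusted), 2 at 24 h, 279 at 48 h, 5 at 72 h and 0 for the difference between times (23 unadjusted). It gave 45 for 72 h against 0 h, 68 for any change in culture, and 1 list in hypoxia in place of 3. It reversed the miR-17-92 median in hypoxia (-0.114), miR-193b* (-0.116), miR-32 (-0.0679) and miR-483-3p (-0.0838) in the mean over times, miR-29b-1* at 12 h (0.187), miR-210 at 48 h (-0.877) and let-7d in culture (0.0184). The miR-210 difference between hypoxia and 8% oxygen at 72 h was 1.61 in place of 3.82. In this setting 21 spots on 3 arrays, 2 of them standard arrays at 48 h, had a local background over 10 times the array's median, and the 10th percentile of the corrected signal was 206 to 708 on these arrays, against 54.6 to 58.6 on the others. With those backgrounds replaced, 51 miRNAs passed in the mean over times, 0 at 12 h (4 unadjusted), 7 at 24 h, 17 at 48 h, 35 at 72 h, 0 for the difference between times (19 unadjusted), 60 for 72 h against 0 h and 74 for any change in culture; let-7d was at 0.0247 and the 8% difference at 1.61. The offset compresses changes of dim miRNAs by construction.

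Scaling to the 75th percentile over all human miRNAs gave 1 call at 12 h, 8 at 24 h and 37 at 48 h. Quantile normalization gave 1 at 6 h, 1 at 12 h and 14 at 24 h, and the percentile outside C19MC 96 in the mean over times and 14 at 24 h. RMA gave 100 in the mean over times, 0 at 12 h (11 unadjusted), 11 at 24 h and an 8% difference of 2.5. The deposited values gave 93 in the mean over times, 1 at 12 h and 11 at 24 h. The scanner software's summary gave 0 at 12 h (10 unadjusted) and a correlation of repeat arrays of 0.979 in place of 0.986, the lowest of the 3. The cause of these shifts was not tested.

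Testing only miRNAs detected on every array gave 0 at 12 h (3 unadjusted), 11 at 24 h, 44 at 48 h, 84 at 72 h, 90 for 72 h against 0 h, 124 for any change in culture and 1 list in hypoxia, with 161 miRNAs tested; it leaves no value for the miR-371 to miR-373 cluster. A floor 4 times lower gave 1 at 12 h, 5 lists in hypoxia and a correlation of repeat arrays of 0.973. Fits of only the 2 groups compared, with fewer samples, gave 9 at 12 h, 8 at 24 h, 37 at 72 h and 48 for 72 h against 0 h. The mean over times from 1 fit gave 106. Without the 0 h array of replicate 2 the difference between times gave 102, and without the 3 arrays of lowest signal it gave 85, with 108 at 48 h. Without a filter, 437 human miRNAs with 1 value on all arrays could not be tested.

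Leaving out each replicate in turn gave 0 (without replicate 2, 83 unadjusted) to 44 calls in the mean over times, with 9 without replicate 1 and 27 without replicate 5. It gave 0 to 1 at 6 h, 0 to 0 at 12 h, 14 to 20 at 24 h, 47 to 57 at 48 h and 83 to 131 at 72 h, with fewer samples in each fit.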

Other observations

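The test without the 0 h array of replicate 2 and the look at neighbouring miRNAs at 48 h were chosen after the result was seen; the other tests in this part were planned before it.

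Some miRNAs transcribed together moved in opposite directions under hypoxia and in culture. The passenger strand miR-23a* did not, but its fall in culture rests on the 0 h arrays. The passenger strand miR-424* lay at or near the floor in both conditions from 6 h on. In the mean over times of hypoxia, miR-23a (-0.27 ± 0.041, adjusted p = 0.0271), its passenger strand miR-23a* (-0.45 ± 0.052, adjusted p = 0.0185) and miR-27a (-0.40 ± 0.079, adjusted p = 0.0433), from a shared precursor with miR-24, were lower in 4 of 4 replicates. From 0 h to 72 h of standard culture, miR-23a (1.44 ± 0.17, adjusted p = 3.2e-08) and miR-27a (1.17 ± 0.13, adjusted p = 6.2e-09) were higher in 4 of 4. In contrast, miR-23a* fell here too (-0.683 ± 0.21, adjusted p = 0.0083, lower in 3 of 4). Its mean level in standard culture was -5.7 at 0 h, -6.72 at 6 h and -6.39 at 72 h, so this fall lay before 6 h. A second pair of this kind was miR-424 and miR-503, neighbours in the genome. In hypoxia miR-424 changed by -0.56 ± 0.054 (adjusted p = 0.0142), with miR-503 at -0.61 ± 0.10 (adjusted p = 0.0334), and in culture miR-424 rose by 1.72 ± 0.19 (adjusted p = 1.1e-08) and miR-503 at least 1.87-fold (adjusted p = 1.5e-07, well above background on 0 of 5 arrays at 0 h and 2 of 4 at 72 h). The passenger strand miR-424* changed by -2.17 ± 0.23 in culture (at least 3.05-fold, adjusted p = 3.4e-09) and by 0.00916 in hypoxia (adjusted p = 0.804). In the hypoxia comparison it was well above background on 4 of 21 hypoxic and 2 of 19 standard arrays. A fall in hypoxia like that of miR-424 could therefore not be seen for it. These miRNAs were singled out after their values were seen, and the 72 h standard arrays enter both comparisons with opposite sign, which alone favours opposite changes. At 48 h of hypoxia, which shares no array with the change from 0 h to 72 h, miR-27a (-0.623, adjusted p = 5.1e-04), miR-424 (-1.24, adjusted p = 1.4e-05) and miR-503 (-1.59, adjusted p = 6.4e-07) were lower in 4 of 4 replicates too, while miR-23a missed the threshold (-0.399, adjusted p = 0.109). With the percentile over all human miRNAs miR-27a missed it as well (-0.482, adjusted p = 0.0626). In the mean over times the call of miR-23a ended with the percentile over all human miRNAs (-0.12, adjusted p = 0.289) and outside C19MC (-0.149, adjusted p = 0.0605), that of miR-27a with the same (0.18 and 0.0574), that of miR-23a* with the percentile outside C19MC (0.0519) and in the deposited values (0.0727), and that of miR-503 with the percentile over all human miRNAs (0.0758) and with quantile normalization (0.086).

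The rise of miR-1290, miR-1246 and miR-1268 in standard culture was the largest in the data, with a median of 4.34 for the 3. Array signal as the whole cause is argued against by a fit with the log2 array signal as a covariate, in which the median rise was 4.32. The 0 h array of replicate 2, the one of lowest signal, is argued against by a median rise of 4.61 without it. The 0 h arrays as a set are argued against too, since from 24 h to 72 h the 3 rose by 1.27 (miR-1246, adjusted p = 6.9e-07), 3.30 (miR-1268, adjusted p = 3.2e-10) and 2.59 (miR-1290, adjusted p = 1.2e-13), a median of 2.59. A rise during culture may be the source, as a hypothesis; whether the probes also bind fragments of other RNAs was not tested.

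Across 350 miRNAs, which are not independent replicates, the change under hypoxia at 72 h ran opposite to the change from 0 h to 72 h in standard culture (r = -0.41, covariance -0.205). Both use the 72 h standard arrays, and simulated unchanged groups gave r = -0.497 and a covariance of -0.0226 (1000 simulations). With 48 h standard arrays for the culture change, r ranged from -0.376 to 0.0186 over the 4 replicates, so shared arrays may account for part, but with both changes from different replicates r stayed between -0.438 and -0.144 in the 6 ways to part them, which argues against shared replicates and against shared arrays as the whole cause. Arrays of low signal are argued against by r = -0.257 without the 3 lowest and with 48 h standard arrays for the culture change, where all arrays gave -0.177. That hypoxia holds back changes of culture stays open: 96 of 151 miRNAs past the threshold from 0 h to 48 h (63.6%) moved the other way under hypoxia at 72 h, but the share was 52.6% to 64.2% over the scalings, below and above the 60% set beforehand, so the test cannot tell.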
